A study of Mus musculus with 2 samples.

How the data were processed

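The data were total RNA-seq of gastrocnemius muscle from female B6CASTF1/J mice aged 4 days, with 1 library from each of 2 biological replicates. Per the labels' protocols, RNA was purified with a tissue RNA kit, 300 ng entered each library, and the spike-in profile was the ERCC set for stranded libraries with reduced ribosomal RNA. Both libraries carry 1 donor record, which may stand for the strain, so whether the animals share a litter is not known.

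For each library the authors deposited a gene table and a transcript table with expected counts (estimated, not always whole) and TPM, and another transcript table with estimated counts and TPM from a separate quantification. Per the file headers and the accompanying notes the genome build was mm10 with GENCODE M21 genes. The aligner and both quantification programs are not given in the sources used here. In the gene tables the effective length was the length minus 99 nt. In the separate transcript tables it was the length minus 349 nt in replicate 1 and 351 nt in replicate 2. Most genes shorter than this took few counts there. Those tables were summed per gene and used as an alternative, called the other quantification. They lacked 86 genes and 95 transcripts of unplaced scaffolds. How strand was treated in counting is not given in the sources used here, so overlapping and antisense genes are uncertain, and so are near-identical copies. Reads of the CAST/EiJ parent were counted on the mm10 reference, which represents C57BL/6J, and alleles were not separated here.

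The gene tables held 55536 Ensembl genes, 26248 tRNA entries and 96 ERCC spike-ins, 71 of which had reads. All Ensembl identifiers matched the GENCODE M21 annotation, from which symbols and coordinates were taken (1-based). Where a symbol had 2 rows, the row with more counts was used for gene lists. Of the gene values, 92.5% and 92.4% were exactly whole in replicates 1 and 2. ERCC spike-ins held 215303 and 268427 expected counts. Exact Clopper-Pearson 95% intervals and the floor of 3 counts for genes at 0 cover counting error only, since reads without molecular identifiers are not independent molecules.

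A gene counted as detected at 1 TPM or more in both libraries. Expected counts were rounded, and edgeR 4.0.16 (R 4.3.3, with limma 3.58.1) gave scaling factors by trimmed mean of M values over genes with a mean of at least 10 counts, log2 ratios of replicate 2 over replicate 1 with a prior count of 2, and the common dispersion of an intercept-only design, whose square root is the biological coefficient of variation. With 1 library against 1, no p-value was given for any ratio. Genes over 2-fold apart were counted by size alone at a mean of at least 100 counts. For each list with at least 3 members at a mean of at least 10 counts, the median log2 ratio was placed among 10000 random lists of equal size drawn from 20 bins of mean expression. Families were described by each member's share of the family TPM per library, transcripts by their share of the gene TPM, and correlations across genes by log2(TPM + 1). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

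The lists, families, thresholds and most alternatives were set before the data were examined. The 32 lists covered myosin heavy chains, fast and slow fibre genes, developmental muscle, sarcomere, myogenic regulators, satellite cells, neuromuscular junction, excitation-contraction coupling, glycolysis, nuclear respiratory chain, mitochondrially encoded genes, fatty acid use, growth and atrophy, matrix, tendon, endothelium, mural cells, Schwann cells, macrophages, neutrophils and lymphocytes, red cells, adipocytes, cartilage and bone, keratinocytes, proliferation, imprinted genes, immediate early and stress genes, circadian genes, abundant noncoding or non-polyadenylated RNAs, a check of sex, and genes with known splicing. Their 387 symbols, with those of the added lists, all matched. After the ratios between libraries had been seen, 5 further lists (bone cells, marrow precursors, liver secreted proteins, liver enzymes, pancreas and gut) were written before their own values were read. Named genes were chosen by a fixed rule: the 15 genes of highest mean TPM and the 10 highest outside the mitochondrial genome, up to 4 members of highest TPM and the members under 1 TPM of each list, every family member, the 10 highest and 10 lowest log2 ratios at a mean of at least 100 counts, the sex check genes, up to 4 members by size of ratio of each list outside its random lists, and the leading transcripts. Other genes named beside these, such as members given as counterexamples, were chosen after their values were seen. A few genes within the rule are withheld and were left out of the text.

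The alternatives were DESeq2 1.42.0 size factors, library size or spike-ins as the scaling, other count and TPM minimums, prior counts and pseudocounts, TPM rescaled without spike-ins and mitochondrial genes, random lists not matched on expression, expected counts in place of TPM, the other quantification, and leaving out each replicate. The ratio step was tested on simulated counts with a coefficient of variation of 10% for 12257 genes, of which 200 were changed. It called 98% of genes changed by 1.5 and 100% of genes changed by 3 on the log2 scale, and made 0 false calls. At that spread few false calls could arise, and reads shared between copies were not simulated. The coefficient of variation, over 17597 genes with a mean of at least 10 counts, came out at 16.5% with the changed genes included, as in the reported estimate, and at 10.1% without them, so genes far apart raise it. The list step, tested over 17581 simulated ratios, placed a list of 8 genes shifted by -1 at a median of -1.01, below all random lists, and an unshifted list at percentile 74.9. Signal tracks and alignments listed in the accompanying notes were not used here.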

Results

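Total RNA was sequenced from the gastrocnemius, the main calf muscle, of female B6CASTF1/J mice aged 4 days. These animals are first-generation hybrids of the C57BL/6J and CAST/EiJ strains. The series held 1 group of 2 libraries, each made from 300 ng of RNA after reduction of ribosomal RNA and addition of ERCC spike-in transcripts. The labels call the libraries biological replicates 1 and 2 and number the animals 3 and 4, while both carry a single donor record. Genes and spike-ins took 30961087 expected counts in replicate 1 and 36246031 in replicate 2. The design held no contrast between conditions, so the questions were which muscle genes and cell types this postnatal tissue expressed and how far the libraries differed. Values are means ± SD over both libraries (n = 2) in TPM (transcript abundance scaled for length and depth) unless stated. With 2 values against 2, an exact two-sided permutation test cannot give a p below 0.333, and the spread between libraries is the measure of error throughout.

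The neonatal gene dominated the sarcomeric myosin heavy chain transcripts. Myh8, which encodes the neonatal chain, reached 4448 ± 405 TPM and took 75.6% ± 0.726 of the TPM of the 9 sarcomeric myosin heavy chain genes. Myh4, the gene of the fast type IIB chain, took 10.3% ± 0.84, and Myh1, the gene of the fast type IIX chain, took 4.39% ± 0.199. The embryonic gene Myh3 took 3.62% ± 0.312, the slow gene Myh7 3.53% ± 0.665 and the fast type IIA gene Myh2 1.55% ± 0.184. Myh6 took 0.835% ± 0.2, and Myh7b and Myh13 were near the bottom with 3.54 ± 0.205 TPM and 2.31 ± 0.389 TPM. The Myh8 level was 7.71-fold that of Myh4 in replicate 1 and 6.96-fold in replicate 2, far apart beside the SD of either gene (exact two-sided permutation p = 0.333, the smallest possible). In genome build mm10, Myh3, Myh2, Myh1, Myh4, Myh8 and Myh13 lie in this order within 293 kb of chromosome 11 (67078300 to 67371586), with Myh8 at 67277124 to 67308634. Myh6 and Myh7 are neighbours of similar sequence on chromosome 14 (54941921 to 54994626), so their values are less certain. The share of Myh1 was 7.14% in the other deposited quantification, and that of Myh6 was 0.247% there and 0.208% by expected counts.

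**Figure D1:**
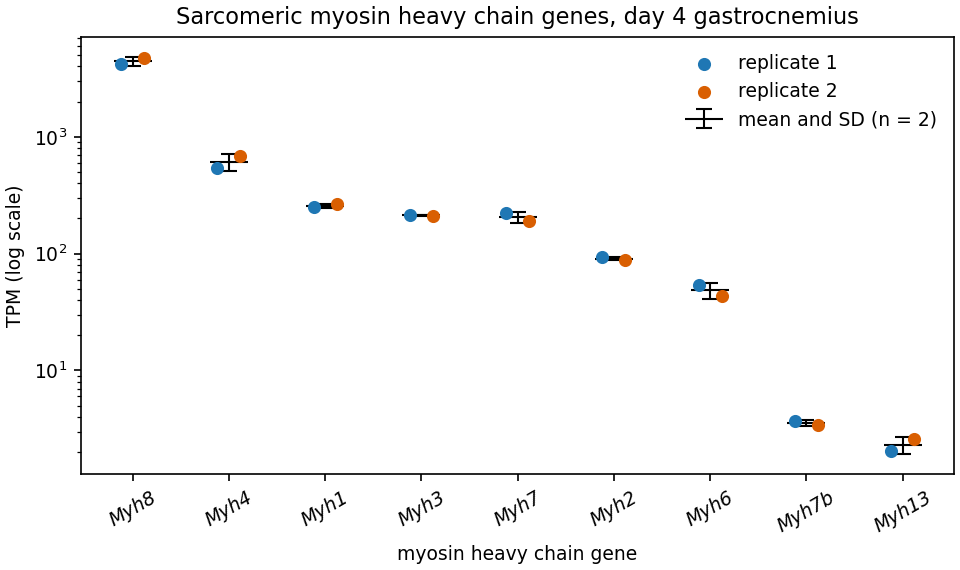
TPM of the 9 sarcomeric myosin heavy chain genes on a log axis, with 1 point per library and the mean and SD of both (n = 2). Myh8 stood at 4162 TPM in replicate 1 and 4735 TPM in replicate 2, and Myh4, the next gene, at 540.1 and 680.0 TPM.

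Fast-twitch genes stood far above slow ones by list median and within the families compared. Outside those families, the fast list gene Mybpc2 (194 ± 26.5 TPM) stood below its paralog Mybpc1 (899 ± 31.8 TPM) of the sarcomere list. The fast list of 12 genes had a median of 2384 TPM, above 99.8% of the 13336 detected genes, and was led by the regulatory light chain gene Mylpf (11454 ± 1406 TPM), the alkali light chain gene Myl1 (6731 ± 623 TPM), the troponin C gene Tnnc2 (3789.5 ± 174 TPM) and the troponin T gene Tnnt3 (3622 ± 271 TPM). The slow list of 10 genes had a median of 157 TPM and was led by Myl2 (268 ± 22.8 TPM), Casq2 (244 ± 13.5 TPM), Myoz2 (195 ± 16.2 TPM) and Tnnt1 (195 ± 21.2 TPM). Within families, the fast member took 95.6% ± 0.382 of troponin I (Tnni2 against Tnni1), 96.5% ± 0.451 of troponin C (Tnnc2 against Tnnc1) and 95.8% ± 0.49 of the sarcoplasmic reticulum calcium pumps (Atp2a1 against Atp2a2). Tnnt3 took 93.2% ± 1.01 of troponin T, the slow gene Tnnt1 5.05% ± 0.868 and the embryonic and cardiac gene Tnnt2 1.76% ± 0.146. Of the myosin light chain genes, Mylpf took 60.95% ± 0.97, Myl1 35.9% ± 0.517, Myl2 1.44% ± 0.276, the embryonic gene Myl4 1.03% ± 0.0622 and Myl3 0.701% ± 0.115. Mylpf was 1.70-fold above Myl1 in TPM, an order that turned with expected counts, where Mylpf held 47.2% and Myl1 49.2% of the light chain counts. Tropomyosin TPM were shared by Tpm2 (54.5% ± 0.483), Tpm1 (42.6% ± 0.0621) and the slow gene Tpm3 (2.94% ± 0.545). In each of these families every fast to slow ratio pointed the same way in both libraries, as did those of the tables by counts and of the other quantification, with the light chain exception given. By expected counts the slow members Tnni1 and Atp2a2 took 6.74% and 6.56%, against 4.36% ± 0.382 and 4.21% ± 0.49 by TPM.

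Structural sarcomere genes and developmental isoforms were expressed together. The 13 genes of the sarcomere list had a median of 662 TPM, led by skeletal actin Acta1 (12814 ± 1627 TPM), muscle creatine kinase Ckm (4448 ± 759 TPM), titin Ttn (1805 ± 139 TPM) and nebulin Neb (936 ± 78.6 TPM). Skeletal Acta1 took 93.6% ± 0.112 of sarcomeric actin and the cardiac form Actc1, which fetal skeletal muscle also uses, took 6.44% ± 0.112, or 4.24% in the other quantification. Ckm took 99.6% ± 0.105 of the creatine kinase pair and the brain form Ckb 0.449% ± 0.105. The developmental list of 9 genes had a median of 68.1 TPM, with Actc1 (882 ± 95.7 TPM) after Myh8, then Myh3 (212 ± 1.01 TPM) and Myl4 (192 ± 8.97 TPM). All 9 were detected, including the myoblast fusion genes Mymk (42.3 ± 4.29 TPM) and Mymx (15.5 ± 1.44 TPM).

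The fetal acetylcholine receptor subunit gene was still above the adult one. Chrng, the fetal gamma subunit, reached 11.8 ± 1.33 TPM and Chrne, the adult epsilon subunit, 4.92 ± 0.587 TPM, a ratio of 2.40 in replicate 1 and 2.38 in replicate 2. That ratio was 3.07 in the other quantification, and Chrng took 80.4% of their counts against 70.5% ± 0.133 of their TPM. All 12 neuromuscular junction genes were detected at a median of 14.04 TPM, led by Utrn (40.6 ± 2.25 TPM), Chrnb1 (39.9 ± 3.66 TPM), acetylcholinesterase Ache (27.98 ± 3.51 TPM) and Chrna1 (17.8 ± 2.60 TPM). The 13 excitation-contraction coupling genes had a median of 72.1 TPM, led by triadin Trdn (235 ± 11.8 TPM), the ryanodine receptor Ryr1 (177 ± 12.7 TPM), Cacng1 (142 ± 16.6 TPM) and the L-type calcium channel gene Cacna1s (123 ± 5.66 TPM). Ryr1 took 86.6% ± 0.374 of the ryanodine receptor pair and Ryr3 13.4% ± 0.374, or 7.44% by expected counts.

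Myogenic regulators and satellite cell markers were also present. The 12 transcription factor genes had a median of 20.02 TPM, led by Mef2c (213 ± 6.43 TPM), Myog (76.6 ± 7.23 TPM), Mef2d (57.2 ± 6.64 TPM) and Myf6 (44.1 ± 10.1 TPM). Pax3 was the 1 member under the detection level, with 5 counts in each library. All 11 satellite cell markers were detected at a median of 11.1 TPM, among them Itga7 (59.3 ± 1.81 TPM), Cdh15 (23.8 ± 2.01 TPM), Sdc4 (23.4 ± 0.247 TPM) and Fgfr4 (18.8 ± 1.49 TPM). The 10 proliferation genes were all detected, with a median of 16.9 TPM, and were led by Pcna (36.5 ± 1.34 TPM), Top2a (35.7 ± 1.96 TPM), Mki67 (27.7 ± 2.11 TPM) and Cdk1 (23.1 ± 2.15 TPM).

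Glycolytic genes lay among the most abundant of the metabolic genes. The 17 glycolysis and glycogen genes had a median of 290.2 TPM, led by Gapdh (2095 ± 281 TPM), Aldoa (1985 ± 264 TPM), Eno3 (1508 ± 248 TPM) and Tpi1 (762 ± 93.04 TPM). The muscle forms prevailed, with Eno3 taking 89.01% ± 1.54 against Eno1, Pgam2 96.5% ± 0.28 against Pgam1 (whose share was 3.47% ± 0.28 by TPM and 7.39% by counts), and Ldha 90.2% ± 0.0616 against Ldhb. The 17 nuclear respiratory chain genes had a median of 167 TPM, led by Atp5b (1239.7 ± 109.9 TPM), Atp5a1 (517 ± 35.8 TPM), Cox4i1 (510.4 ± 38.8 TPM) and Cox8b (298 ± 10.996 TPM). The muscle form Cox6a2 took 72.1% ± 3.32 against Cox6a1 and Cox8b 64.1% ± 0.505 against Cox8a, while the muscle form Cox7a1 took 34.3% ± 0.0601 against Cox7a2, or 20.1% in the other quantification. The 12 fatty acid genes had a median of 91.3 TPM, led by Cd36 (171 ± 2.91 TPM), Fabp3 (168 ± 8.99 TPM), Acadl (166 ± 14.7 TPM) and Lpl (128 ± 4.57 TPM). The 13 mitochondrially encoded protein genes had a median of 1594 TPM, led by mt-Co1 (6047 ± 14.98 TPM), mt-Cytb (3091 ± 210.5 TPM), mt-Nd1 (2879 ± 282 TPM) and mt-Atp8 (1971 ± 494 TPM). Values of mt-Co2, mt-Atp6 and mt-Co3 are uncertain, since near-identical copies on chromosome 1 took most of their counts in the gene tables. In the other quantification mt-Atp6 held 83.1% of the sum with its copy and reached 8207 TPM against 1684, while the short gene mt-Atp8 had 0 TPM. The order of the mitochondrially encoded genes is therefore uncertain. The copy Gm28661 (24614885 to 24615565) held 123799 counts in replicate 1 against 1044 for mt-Co2 itself.

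The imprinted fetal growth genes were among the highest in the tissue. The noncoding RNA gene H19 (7504 ± 743 TPM) and the growth factor gene Igf2 (5050.4 ± 807 TPM) led the 15 imprinted genes, followed by Meg3 (2294 ± 472 TPM) and Rian (2052 ± 17.3 TPM), and the list had a median of 297 TPM. Phlda2, with 4 counts and 1 count, was the 1 imprinted gene under the detection level. H19 (142575529 to 142578143) and Igf2 (142650766 to 142666816) lie with the fast troponin genes Tnni2 (142441808 to 142444410) and Tnnt3 (142498836 to 142516009) within 225 kb of chromosome 7. The parental origin of these reads was not analysed here. The 11 growth and atrophy genes had a median of 16.4 TPM, with Igfbp5 (129 ± 0.431 TPM), Igf1 (66.7 ± 2.91 TPM) and Mstn (25.1 ± 1.93 TPM), the muscle growth inhibitor gene, after Igf2.

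Of the lists for other cell types, the matrix and fibroblast list had the highest median level. Such medians depend on the genes chosen and do not rank the amounts of the cells. The 14 matrix and fibroblast genes had a median of 258 TPM, led by Col1a1 (2566 ± 544 TPM), Col3a1 (2085 ± 0.0141 TPM), Col1a2 (1508 ± 348 TPM) and Sparc (919 ± 95.8 TPM). The mural list of pericyte and smooth muscle genes had a median of 25.6 TPM, led by Acta2 (143 ± 2.41 TPM), Rgs5 (47.1 ± 2.69 TPM), Tagln (31.8 ± 1.75 TPM) and Notch3 (25.6 ± 1.18 TPM), and the endothelial list had a median of 20.8 TPM, led by Cdh5 (64.8 ± 3.62 TPM), Egfl7 (63.98 ± 18.5 TPM), Pecam1 (47.4 ± 1.53 TPM) and Cldn5 (22.1 ± 1.19 TPM). Schwann cell genes had a median of 9.36 TPM, with the myelin genes Pmp22 (132 ± 15.1 TPM), Mbp (60.03 ± 15.3 TPM) and Prx (12.8 ± 1.84 TPM). Macrophage genes had a median of 14.6 TPM, led by Lyz2 (25.4 ± 5.24 TPM), Mrc1 (20.6 ± 1.65 TPM), Csf1r (17.5 ± 0.679 TPM) and C1qb (15.7 ± 0.651 TPM). The adipocyte list had a median of 20.6 TPM, led by Fabp4 (245 ± 39.6 TPM), Cfd (52.8 ± 9.58 TPM), Adipoq (34.9 ± 4.19 TPM) and Plin1 (30.4 ± 9.02 TPM), and the brown fat gene Ucp1 had 15 and 2 counts.

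Genes of blood, bone, tendon and liver were among those furthest apart between the libraries. Red cell genes were lower in replicate 2 in 8 of 8 cases, with a median of 58.7 TPM in replicate 1 and 13.5 TPM in replicate 2 and a median log2 ratio of -2.46 (replicate 2 over replicate 1). Beta globin Hbb-bs had 8968 and 1861 counts in replicates 1 and 2, alpha globin Hba-a1 9354 and 2086, Hba-a2 5255 and 1179 and Hbb-bt 1587 and 465 counts, values made uncertain by near-identical paralogs. The anion exchanger gene Slc4a1 had 1721 and 226 counts and Hemgn 172 and 15. The neutrophil and lymphocyte list was lower in 7 of 7 measured members, at a median log2 ratio of -2.05, led by the calprotectin genes S100a9 (365 and 72 counts) and S100a8 (266 and 56), then Ltf (225 and 60) and Ngp (170 and 48). The lymphocyte gene Cd79a had 46 and 5 counts, and Cd3e and Ms4a1 were under 1 TPM in both libraries. The cartilage and bone list was lower in 7 of 8 measured members, at a median log2 ratio of -2.20. Setting its measured members at 0 to their bound could not move this median, since they were the lowest of the list. In that list Ibsp, a bone matrix gene (chromosome 5, 104299171 to 104311469), had 471 counts in replicate 1 and 0 in replicate 2, at least 178-fold lower against a floor of 3 counts, and Col10a1 had 70 and 0, at least 26.4-fold lower. Bglap had 48.7 and 5 counts and Sp7 47 and 7, while Sox9 had 130 and 155, Col2a1 2276 and 1188 and Acan 669 and 491. Col10a1 and Sp7 were under 1 TPM in both libraries, as was Matn1 with 1 count and 0. All 7 tendon genes were lower in replicate 2, at a median log2 ratio of -1.04, led by tenomodulin Tnmd (101.01 and 48.98 TPM), Thbs4 (71.8 and 58.2 TPM), Fmod (87.96 and 41.6 TPM) and Kera (34.4 and 15.1 TPM), with Comp at -1.28 and Mkx at -0.67 on the log2 scale. Each of these 4 lists lay below all 10000 random lists of equal size matched on mean expression, which describes these libraries and is no test of conditions. Median levels over both libraries were 36.1 TPM for red cell, 24.7 TPM for tendon, 2.37 TPM for neutrophil and lymphocyte and 1.19 TPM for cartilage and bone genes.

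Over the 12256 genes with a mean of at least 100 counts, 88 were over 2-fold apart, 31 higher and 57 lower in replicate 2. With spike-in scaling, which moved the median of all genes by -0.14 on the log2 scale, the split was 26 higher and 80 lower. The 10 lowest log2 ratios belonged to the small nuclear RNA gene Gm24497 (-9.75), Ibsp, the collagenase gene Mmp13 (214 and 0 counts, at least 80.7-fold lower), osteopontin Spp1 (-4.81), Mmp9 (-3.71), Chtf8 (-3.50), Slc4a1 (-3.09), Ctse (-2.79), Gm10222 (-2.70) and Stfa1 (-2.67). Genes of liver proteins made up 8 of the 10 highest, namely Apob (3.87), alpha-fetoprotein Afp (3.55), Fga (3.48), Apoa1 (3.36), albumin Alb (3.35), Pzp (3.23), Ahsg (3.23) and Kng1 (2.96), with Fam220a (3.36) and the pseudogene Gm5559 (3.15). Alb (chromosome 5, 90460897 to 90476602) had 254 and 2941 counts in replicates 1 and 2, and Afp (chromosome 5, 90490737 to 90508907) 63 and 857. In the other quantification 76 genes were over 2-fold apart, of which 57 were shared with the 88 and had the same direction. Chtf8 and Fam220a had the opposite sign there, and Gm24497, Gm10222 and Gm5559, which share sequence with other loci or are short, had mean counts of 0, 0 and 5.74 there. The count depended on depth, with 660 genes at a mean of at least 10 counts and 14 at a mean of at least 1000.

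**Figure D2:**
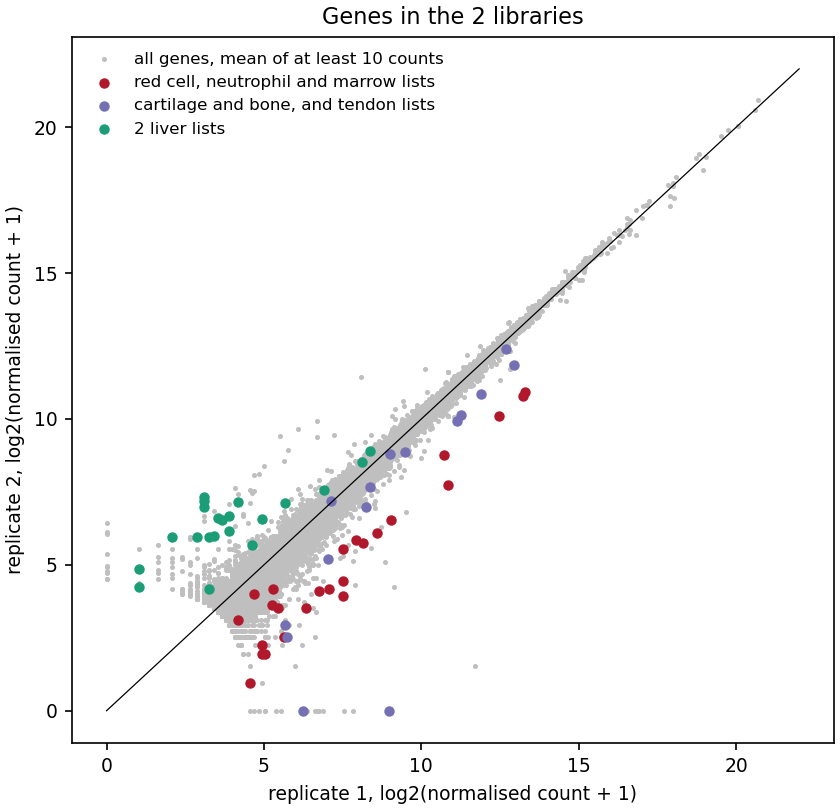
Counts of each gene in replicate 1 (x) and replicate 2 (y) after scaling by trimmed mean of M values, as log2(count + 1), for genes with a mean of at least 10 counts, and with the diagonal drawn. Red cell, neutrophil and marrow genes (red) and cartilage, bone and tendon genes (purple) lay mostly below the diagonal, with red cell genes at a median log2 ratio of -2.46, and liver genes (green) above it, at 2.68 for secreted proteins.

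Fast fibre, sarcomere and glycolysis genes were higher in replicate 2, by far less, and with spike-in scaling by only 0.09, 0.07 and 0.08 in median log2 ratio. The fast list was higher in replicate 2 in 12 of 12 members at a median log2 ratio of 0.23, with 0.39 for the calcium buffer gene Pvalb, 0.32 for Actn3, 0.29 for Myoz1 and 0.28 for Mybpc2. The sarcomere list was at 0.21 (12 of 13 higher), with Ckm at 0.34, Ldb3 at 0.28, Acta1 at 0.27 and Des at 0.25, and the developmental list at 0.19 (7 of 9), with Chrng at 0.25, Actc1 at 0.23, Mymk at 0.21 and Mymx at 0.20, although in the other quantification this list, at 0.14, lay within its random lists. Glycolysis was at 0.22 (16 of 17, with Eno3 at 0.34, Ldhb at 0.28, Pygm at 0.27 and Tpi1 at 0.27), nuclear respiratory chain genes at 0.15 (16 of 17, with Cox6a2 at 0.24), and fatty acid genes at 0.16 (11 of 12, with the kinase gene Pdk4 at 0.72). Myogenic regulators were at 0.20 (10 of 11, with Myf6 at 0.48 and Myod1 at 0.38), satellite cell markers at 0.14 (8 of 11, with Msc at 0.61, within unmatched random lists), neuromuscular junction genes at 0.18 (10 of 12, with Chrnd at 0.53) and imprinted genes at 0.18 (12 of 14, with Peg10 at 0.43 and Meg3 at -0.50). Schwann cell genes were at 0.29 (7 of 9), with Sox10 at 0.65, Erbb3 at 0.56 and Mbp at 0.45. The slow list, at -0.06 (6 of 10 lower, Csrp3 at 0.50 and Tnnt1 at -0.22), the matrix list at -0.06 (10 of 14 lower, Col1a2 at -0.45 and Col1a1 at -0.43) and the mitochondrially encoded genes at -0.11 (9 of 13 lower) lay below their matched random lists but within unmatched ones. The adipocyte list, at -0.34, lay below both kinds (5 of 7 lower, Lep at -1.17 and Plin1 at -0.52). The mean over the mitochondrially encoded genes was 0.05 and that over the slow list 0.002, opposite in sign to their medians, with mt-Co2 at 1.58.

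Within their central 95% of random lists lay the myosin heavy chains (-0.005), excitation-contraction coupling (0.13), growth and atrophy (0.05), endothelium (0.12), mural cells (0.02), macrophages (-0.10) and proliferation (-0.06). In all, 13 of 30 lists lay above and 10 below the central 95% of their random lists, where 1.5 would lie outside by chance if members moved independently, which members of 1 tissue do not. With spike-in scaling every list median was lower by about the shift of all genes. Nuclear respiratory chain genes then stood at 0.01, fatty acid genes at 0.01 and satellite cell markers at 0.0008, near 0, and the sign turned for excitation-contraction coupling (-0.007), growth and atrophy (-0.09), endothelium (-0.03) and mural cells (-0.12). Relative to all genes the same 23 lists lay outside, which was nearly fixed in advance because this scaling moved all genes nearly alike.

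**Figure D3:**
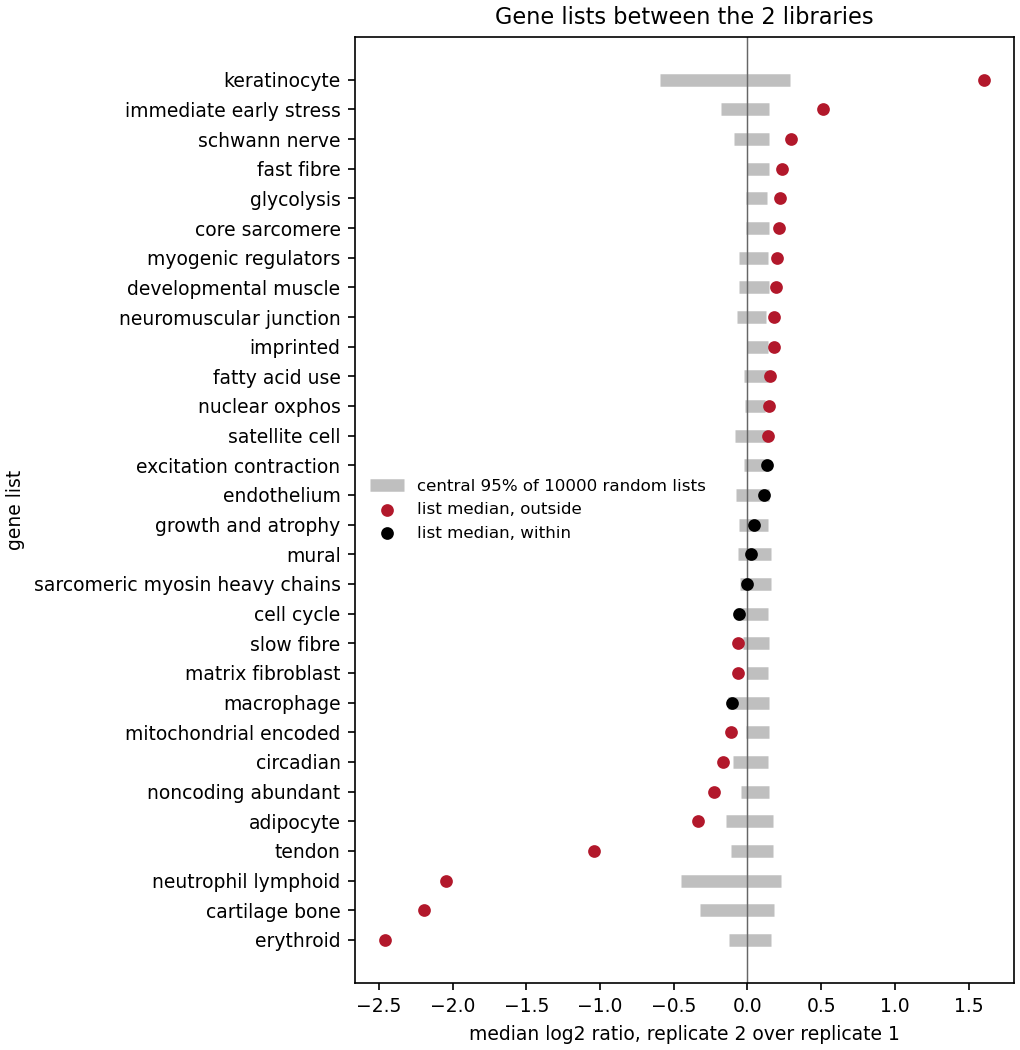
Median log2 ratio of replicate 2 over replicate 1 for the 30 gene lists fixed before the data were examined (points), with the central 95% of 10000 random lists of equal size matched on mean expression (grey bars). Red points lie outside their bar, black points inside, from -2.46 for red cell genes to 1.60 for skin keratinocyte genes, whose median level was 0.615 TPM.

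Transcript models within a gene were resolved unevenly. In 13 of 20 genes with known splicing in muscle, the same transcript led in both deposited quantifications. Those included Tpm1-205 (94.6% ± 0.953 of the Tpm1 TPM, 73.03% in the other quantification), H19-202 (89.1% ± 0.0201 and 82.1%), Ryr1-202 (82.1% ± 2.51 and 74.4%), Tpm3-205 (66.4% ± 0.519 and 69.6%), Ldb3-207 (62.3% ± 0.988 and 55.8%), Bin1-205 (61.6% ± 1.68 and 50.8%), Mef2a-208 (55.1% ± 0.213 and 44.97%), Mef2d-201 (49.7% ± 1.27 and 46.7%) and Tpm2-202 (40.4% ± 0.211 and 45.1%). Fn1-201, Cacna1s-204 and Mef2c-201 led their genes with 34.04% ± 3.22, 34.3% ± 3.87 and 31.1% ± 1.37, or 33.6%, 59.02% and 25.3% in the other quantification. By expected counts Mef2c-201 held 58.2% and Tpm2-202 72.7%. The calcium pump gene Atp2a1 divided into Atp2a1-201, which encodes 994 amino acids, at 69.9% ± 0.000853, and Atp2a1-202, a model of 145 amino acids, at 30.1% ± 0.000853, or 6.90% by expected counts. The glycolytic gene Pkm was divided evenly between Pkm-202, with the upstream alternative exon of the muscle M1 form (chromosome 9, 59675029 to 59675195), at 47.7% ± 1.18, and Pkm-201, with the downstream exon of the M2 form (59675568 to 59675734), at 47.7% ± 0.612. The other quantification gave 40.5% and 48.5%, so which form led was not settled. The leading transcript also differed in Tnnt3, where Tnnt3-215 held 26.4% ± 0.128 in 1 quantification and 0% in the other, and in Tnnt1, Clcn1, Ttn, Neb and Igf2, whose leaders Tnnt1-203, Clcn1-201, Ttn-215, Neb-204 and Igf2-208 held 32.4% ± 0.638, 42.3% ± 2.06, 20.7% ± 0.686, 25.2% ± 0.799 and 22.1% ± 0.959, or 13.3%, 28.1%, 7.88%, 16.05% and 15.4% in the other quantification. By expected counts other transcripts led in Ttn (Ttn-205 with 54.8, against 1.25 for Ttn-215, in percent of counts), Neb (Neb-202 with 60.6, Neb-204 2.54), Igf2 (Igf2-205 with 37.4, Igf2-208 9.59), Ldb3 (Ldb3-205 with 55.6, Ldb3-207 33.8) and Pkm (Pkm-201 with 53.4, Pkm-202 44.5).

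Short noncoding RNAs set the TPM scale of these libraries. The signal recognition particle RNA genes Rn7s1 and Rn7s2, identical copies on chromosome 12 with equal values, held 180134 ± 1305 TPM each and together 36.03% ± 0.261 of all TPM, but 6.45% ± 0.19 of the counts. After them came the mitochondrial ribosomal RNA mt-Rnr2 (35957 ± 372 TPM), Rn7sk (32414 ± 3968 TPM), mt-Rnr1 (20769 ± 722 TPM) and Acta1. Next were Gm26917 (12077 ± 765 TPM), Mylpf, the ribonuclease P RNA Rpph1 (9947 ± 854 TPM) and H19. Gm26917 is annotated as a long noncoding RNA gene, and the source of its reads was not tested. Gm28661, Myl1, mt-Co1, Gm10925 and Igf2 completed the 15 highest. The mitochondrial genome took 8.12% ± 0.196 of TPM, or 14.2% in the other quantification, which listed nearly no short genes. The median TPM of 27 of the 30 gene lists was over 1.5 times higher there, such as 3951 for fast and 112 for red cell genes. The mitochondrial share of counts was 8.63% (95% interval 8.62% to 8.64%) in replicate 1 and 8.14% (95% interval 8.13% to 8.15%) in replicate 2 by exact binomial intervals, which cover counting error only. Counts on the near-identical copies on chromosome 1, such as 123799 on Gm28661 in replicate 1, are left out of this share. Nuclear protein-coding genes took 74.9% ± 0.848 of counts and 38.7% ± 1.28 of TPM, and spike-ins took 0.695% (95% interval 0.692% to 0.698%) and 0.741% (95% interval 0.738% to 0.743%) of counts.

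In all, 13336 of 55536 Ensembl genes reached 1 TPM in both libraries, 12064 of them protein-coding. Across 13876 genes with a mean of at least 1 TPM, which are not independent replicates, log2(TPM + 1) of the libraries correlated with Pearson r = 0.982 and Spearman rho = 0.981. The biological coefficient of variation estimated over 17598 genes was 12.7%, with the genes far apart included. As a check for a single library deposited under both names, their counts gave a chi-square of 299849 on 17597 degrees of freedom over these genes, or 17.04 per degree of freedom against about 1 for a repeat.

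Sex-linked genes were read as a check of the female label. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), had 33131 and 29471 counts and 71.4 ± 13.7 TPM. Of the Y-linked genes, Uty had 2 and 0 counts, Ddx3y 1 and 0, and Kdm5d and Eif2s3y 0 in both, where a count of 0 allows up to 0.0976 CPM in replicate 1 and 0.0834 in replicate 2. The other quantification listed Uty at 1.74 TPM and Kdm5d at 0.551 TPM. Tsix, antisense to Xist, had 7.81 and 4 expected counts.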

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

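The scaling test, the test on the tendon and cartilage lists and both tests on short genes were chosen after their results had been seen, while the tests on the 5 added lists were written before those lists' values were read. Apart from a change of plasma protein genes alone, no biological explanation was tested for any pattern, since the design has 1 group. Reads in entries outside the comparisons, above the limit that 0 reads allow, came from the phage phiX, a sequencing control (24 reads in replicate 1 and 41 in replicate 2), and from the tRNA entries (4 reads in each library).

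Red cell, neutrophil, bone and tendon genes were lower in replicate 2, with Hbb-bs, the highest in TPM, at 8968 and 1861 counts in replicates 1 and 2. The red cell median stayed at -2.46 or lower under all 4 scalings. The scalings moved genes nearly alike, by -0.14 on the log2 scale with spike-ins and by less with the others. The choice of scaling was thus too small to account for the pattern, an outcome that was fixed in advance. By the rule set beforehand, the bone cell list, at a median of -0.41, met what blood left in the tissue as the sole cause predicts (above -0.5). It did so by less than its median absolute deviation of 0.26 and lay below its random lists (percentile 0.1). That margin was not in the rule and was weighed afterwards, so the bone cell list by itself leaves blood as the sole cause undecided. The tendon and the cartilage and bone lists were low as well, the higher of their medians being -1.04 with a median absolute deviation of 0.24. The cartilage and bone median was -2.20 with a deviation of 1.33. Measured members were lower in 7 of 7 cases for tendon and 7 of 8 for cartilage and bone. Being part of the pattern itself, these lists are no separate test, but they show that it went beyond blood genes. For tendon, cartilage and bone genes, these values argue against blood as the sole cause. Blood stays open for red cell and neutrophil genes. For bone with its marrow in the replicate 1 sample, the marrow precursor list (median level 0.565 TPM) had a median of -2.66. Of its measured members 10 of 10 were lower, and none was detected in both libraries. The bone cell list (0.825 TPM), 3 of whose 12 genes were detected in both, had 7 of 8 members lower at a median of -0.41. As this lies above -0.5, the rule written beforehand went against bone with its marrow. The gap was less than the same deviation, which is a spread over members and was not in the rule, so bone is left open here. Members of the bone cell list ranged from Runx2 at -2.05 and Smpd3 at -1.15 to Ctsk, the most abundant, at -0.63 and Itgb3 at 0.32. Differing amounts of blood, tendon and bone in each dissection may each hold a part.

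Liver genes were higher in replicate 2, with Alb at 254 and 2941 counts, Afp at 63 and 857 and Apob at 42 and 723 in replicates 1 and 2. A change of plasma protein genes alone was argued against by the list of intracellular liver enzymes (median level 0.255 TPM), whose median log2 ratio was 2.70 with 7 of 7 measured members higher, among them Cyp2e1 (13.2 and 73.97 counts) and Cps1 (9 and 67), while the other 7 of 14 had a mean under 10 counts, such as Hal (9 and 10) and Kynu (2 and 1), and none was detected in both libraries. RNA of abdominal organs in general was argued against by the pancreas and gut list, where 0 of 10 members reached a mean of 10 counts. Liver RNA in the replicate 2 library is consistent with both liver lists, the lower of whose medians was 2.68, with 14 of 14 measured secreted protein genes higher (median level 1.09 TPM), although 3 of its 15 genes (Hp, Vtn and Rbp4) were also detected in replicate 1 and Apoc3 had 1 and 2 counts. Whether such RNA came with the tissue or by exchange of reads between libraries was not tested.

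Short genes were near 0 in the other quantification, where Rn7sk had 0 TPM against 32414 in the gene tables and mt-Atp8 0 against 1971. Of 107 genes with at least 100 counts that were shorter than the mean assumed length of 350.1 nt, 97.2% kept under 10% of their count there. The share was 28.4% of 208 genes between that length and 1.5 times it, and 0.486% of 11936 longer genes. This order goes with a fragment length longer than these RNAs. Reads shared between copies stay open as a part of it, since only 7 short protein-coding genes of unique symbol could be examined, of which 57.1% were lost.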

How the results depend on the processing

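The other quantification and the choice of counts or TPM moved levels, shares and ratios. One choice was changed at a time, and leaving out the red cell, marrow, bone, tendon and liver lists was added after seeing the data. The number of detected genes stayed within 1.5 times of 13336 under every alternative. The coefficient of variation ranged from 10.7% to 15.4%, and was 11.6% without those lists, where 71 genes were over 2-fold apart. That count was 660 with a minimum mean of 10 counts and 14 with a minimum of 1000, as more or fewer low-count genes entered, and 76 to 106 under the scalings, prior counts and the other quantification. Pearson r across genes was 0.963 and 0.935 with pseudocounts of 0.1 and 0.01, which give low genes more weight, and 0.993 without a filter. With expected counts in place of TPM, the Myh8 share was 77.4%, the log2 ratio of Chrng over Chrne 2.03, the Pkm-202 share 44.5% and the mitochondrial share 8.39%. With the other quantification these were 74.0%, 1.62, 40.5% and 14.2%, and with a pseudocount of 1 TPM the Chrng ratio was 1.11. The log2 ratio of Mylpf over Myl1 reversed to -0.0582 with expected counts, which are not divided by transcript length. The cause of the other moves was not tested. Without replicate 1 or 2 these ranged from 75.1% to 76.1%, 1.25 to 1.27, 46.9% to 48.6% and 7.98% to 8.25%, and 16 to 18 lists had medians above the upper quartile of detected genes, against 16, and 19 did with the other quantification. List medians in TPM were over 1.5 times higher there in 27 of 30 lists, with 3951 for fast, 584 for glycolysis, 141 for developmental and 112 for red cell genes. Of 30 lists, 23 lay outside their random lists under each scaling and prior count. For the scalings this was nearly fixed in advance, since each moves a list and its random lists nearly alike. With the other quantification 22 did, as the developmental list, at 0.14, lay within. With unmatched random lists 19 did, 18 of them shared. There the slow, satellite cell, mitochondrially encoded, matrix and circadian lists lay within and excitation-contraction coupling outside. No other ratio within a family reversed. No paired analysis was possible because there is 1 group. A fit without 1 replicate leaves 1 library, so the coefficient of variation and the ratios between libraries had no such value.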

Other observations

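The sums over copies given here were chosen after the results had been seen, and the lists before. Immediate early, clock and abundant noncoding or non-polyadenylated RNA genes also separated the libraries. The immediate early and stress list was higher in replicate 2 in 10 of 10 members, at a median log2 ratio of 0.51 and a median level of 4.93 TPM, with Fosb at 1.39, Fos at 1.02, Jun at 0.74 and Hspa1b at 0.64, the last of a near-identical pair. Its most abundant members were Jun (16.9 ± 5.98 TPM), Dusp1 (11.99 ± 1.39 TPM), Egr1 (8.95 ± 2.77 TPM) and Ier2 (7.58 ± 1.03 TPM). The circadian list was at -0.16 with 8 of 11 members lower, at a median level of 8.70 TPM, within unmatched random lists, with Per1 at -0.94, Dbp at -0.43, Nr1d1 at -0.39 and Per3 at -0.36, and was led by Tef (43.5 ± 0.615 TPM), Nr1d2 (17.7 ± 1.55 TPM), Per1 and Nr1d1. The abundant noncoding list also held the protein-coding histone genes Hist1h1b, Hist1h1c and Hist1h1e, as non-polyadenylated RNAs. It was lower in 10 of 11 members at -0.23, with a median level of 139 TPM, the value of Hist1h1e. The nuclear RNA Neat1 was at -0.96, Malat1 (2279 ± 683 TPM) at -0.61, the mitochondrial RNA processing gene Rmrp (4041 ± 1056 TPM) at -0.53 and Snhg1 at -0.34. The times of dissection were not used here, and no explanation was tested for these lists.

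Skin keratinocyte genes were low in both libraries, at a median of 0.615 TPM, and higher in replicate 2 in 4 of 5 measured members, at a median log2 ratio of 1.60. Krt14 had 3 and 34.7 counts in replicates 1 and 2, Krt15 1 and 13, Krt1 20 and 90, Krt5 12.9 and 49 and Krt10 47 and 110, while Trp63 had 282 and 308. The 20 genes with known splicing in muscle were at 0.19, with a median of 354 TPM. Some large ratios arose where copies share reads. Rnu3a, on 2 rows, stood at -1.33 and 2.67, while the ratio of their summed counts was -0.08. For mt-Co2 the log2 ratio was 1.58 alone and -0.11 when summed with Gm28661.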
